A study of Homo sapiens with 8 samples.

How the data were processed

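Chromatin immunoprecipitation with sequencing (ChIP-seq) was analysed for the tumour suppressor p53 in 293T cells, a human embryonic kidney line that carries the simian virus large T antigen, a protein that binds p53. Per the labels, cells received doxorubicin at 0.5 µg/ml (Dox) or the vehicle phosphate-buffered saline (PBS) for 24 h, and chromatin was precipitated with a p53 antibody. The labels name 8 samples: 4 ChIP libraries, 2 per condition, and 4 input samples. Replicate number 1 came from passage 3 and replicate number 2 from passage 5 in both conditions, so number and passage cannot be told apart. The libraries of a condition thus came from cells of different passages, and p-values measure the spread between these samples, passage included. Whether the Dox and PBS libraries of a replicate number shared a culture or were handled together is not given in the sources used here. The input samples were not analysed here.

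Reads were processed with BWA and MACS2 on build hg19, per the submitters' processing notes, and versions and filters are not given in the sources used here. The authors deposited 1 MACS2 peak list per ChIP library, called separately and not on pooled reads. The peak names in the deposited lists state a calling threshold of p under 0.05, and the lists were not limited by q. Each deposited peak carries a fold enrichment at its summit over the caller's local background, which is the authors' own ratio and was used only to describe, rank or filter peaks within 1 list. The deposited lists also give the p-value and the q-value of each peak as −log10. The last column of the deposited lists holds the summit position as a chromosome coordinate. The authors also deposited 1 table per condition of peak pairs matched between the replicates, with the −log10 p-value of both peaks. Per the file headers, each pair has an irreproducible discovery rate (IDR), a q-value for a pair not being reproducible, and a local IDR, a fraction that was read but not used. Whether those tables had been limited to an IDR is not given in the sources used here, so this was checked on the values. Of the Dox replicate 1 peaks that overlapped Dox replicate 2, 9150 of 9153 lay in a listed pair, and of the PBS replicate 1 peaks that overlapped PBS replicate 2, 6597 of 6602. IDR reached 0.586 for Dox and 0.646 for PBS and was above 0.05 in 72.5% and 85.0% of the pairs. The tables were therefore used as nearly all overlapping pairs, not as pairs that passed a strict IDR.

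Read depth is not given in the peak lists. The fold and p of a MACS2 peak move in steps of whole reads, and from these steps the ChIP background height (reads after extension over a typical position), the ratio of ChIP to control reads and each peak's summit height were estimated. The ChIP background height came to 3.03 reads in Dox replicate 1, 3.07 in Dox replicate 2, 2.73 in PBS replicate 1 and 2.65 in PBS replicate 2. The ChIP-to-control ratio came to 3.75, 3.05, 5.37 and 2.77 in the same order. Heights were resolved for 98.2% to 99.3% of peaks, and the lowest peak stood 2.64, 3.26, 4.02 and 3.4 times above background in the same order. A common minimum height of 4.02 times background, the strictest of the 4, was used as an alternative for all lists. On simulated lists with the same background and ratio both were recovered, 96.0% to 99.7% of heights were resolved, and 100.0% of those were correct. The simulated lists were made with the formulas for fold and p that the estimate assumes. They thus tested the calculation, and not whether the deposited values follow those formulas. In the deposited lists, the p of 18.2% to 63.5% of peaks lay on the steps of the estimated background. The overlap and site steps, tested on 7435 planted sites, put 0 in a wrong pattern.

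Peaks counted as overlapping when they shared at least 1 bp. Chance overlap came from 100 circular shifts of 1 list by a random offset per chromosome, with a fixed seed. The shifts can place peaks in stretches where no list has peaks, and do not keep them in regions where peaks concentrate. Overlap above this level is therefore not specific to p53. The matched pairs of a condition were merged into regions, which were called shared, Dox-only or PBS-only by overlap with the regions of the other condition. The peaks of the 4 library lists were merged into sites, and each site was marked present or absent in each library. The number of sites found in both libraries of a condition and in neither library of the other was set beside the same number for the other splits of the 4 libraries, by replicate number and crossed. Mean peak counts were compared with a two-sided exact permutation test, for which 2 libraries against 2 allow no p below 0.33. Shares of a list carry 95% Wilson intervals, which cover counting error only and treat peaks as independent. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

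Before the data were examined, the tests, the alternatives and the rule for named sites were fixed. For sites, the rule took the 10 with the highest mean percentile of fold enrichment in each of the shared, Dox-only and PBS-only sets. They were taken among sites with a peak in both libraries of the condition, or in all 4 libraries for the shared set. They were named by position where no annotation was at hand. The rule also named the genes CDKN1A and MDM2 in every case, and leading genes of fixed lists of p53 targets. That part needs an annotation and was not run. An hg19 sequence or annotation was not used here. Lists of p53 target genes fixed in advance, with the p53 motif and the location of peaks relative to genes, were therefore not analysed here, and sites are named by position on hg19. Coordinates count from 1.

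Some analyses were chosen after the data were seen. These were the common minimum height, the IDR limit of 0.05, the ranking by p, the overlap by rank, the sites with q of at most 0.05, the chromosome shares, the dense windows with the distances between summits, and the sites at chromosome starts. Lists of the top 500, 1000, 2000 and 5000 peaks and −log10 q minimums of 1, 1.3, 2 and 3 were also tried along the way. The limit of q at most 0.05 for strong sites was chosen after the counts at those 4 minimums had been seen.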

Results

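Binding of p53 to chromatin was mapped by ChIP-seq in 293T cells given doxorubicin, a topoisomerase poison that causes DNA breaks and is widely used to activate p53, or PBS as the vehicle. The comparison addresses where p53 peaks were called at baseline and after 24 h of doxorubicin. A called peak does not by itself show that p53 was bound there. Peaks with q of at most 0.05 made up 3.65% and 4.84% of the lists of Dox replicates 1 and 2. For PBS replicates 1 and 2 the shares were 2.56% and 5.84%. The p53 motif was not searched, and peaks in repeated or artefact-prone sequence were not removed here. There were 2 libraries per condition, and the lists held 46658 and 16642 peaks for Dox replicates 1 and 2, and 11304 and 22978 peaks for PBS replicates 1 and 2. The depth of sequencing is not given, and the estimated ChIP background height was 2.65 to 3.07 reads over the 4 libraries. Sites are given by position on hg19, and fold enrichments are the authors' own values within each list.

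Of the 100 peaks with the smallest p in each list, 100 in Dox replicate 1, 99 in Dox replicate 2, 97 in PBS replicate 1 and 97 in PBS replicate 2 overlapped a peak in all 3 other libraries. The leading shared sites were taken from sites with a peak in all 4 libraries, so their presence in both conditions follows from the choice. The first, on chromosome 11 from 65190036 to 65191612, had an enrichment of 26.4-fold and 22.4-fold in Dox replicates 1 and 2 and of 14.9-fold and 17.9-fold in PBS replicates 1 and 2. It was followed by sites on chromosome 17 from 43225665 to 43227581, with enrichments between 14.4-fold and 22.3-fold, and on chromosome 1 from 181103884 to 181104610, with enrichments between 17.9-fold and 22.9-fold. The other leading shared sites lay on chromosome 1 (148603540 to 148605108), chromosome 12 (120728497 to 120731197), chromosome 21 (34739337 to 34740256), chromosome 6 (36643749 to 36644624) and chromosome 17 (56708025 to 56709297, 8075582 to 8077118 and 56735201 to 56736900). Each of these 10 sites ranked at or above the percentile 99.7 of fold enrichment in each of the 4 lists. The site on chromosome 6 had 11.9-fold and 13.3-fold enrichment in the Dox libraries and 11.9-fold and 13.2-fold in the PBS libraries. Folds of different lists are on scales set by each library and its control, so the values describe each list and no difference between conditions was drawn from them.

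The overlap fell with rank in every pair of libraries. Of the Dox replicate 1 peaks ranked 5001 to 10000, 37.8% (95% Wilson interval 36.5 to 39.2 per cent) overlapped a peak of Dox replicate 2, and 48.5% (47.1 to 49.9) overlapped a peak of PBS replicate 2, which has the longer list of these partners. For PBS replicate 1 peaks of the same ranks, the share was 51.5% (50.1 to 52.9) with PBS replicate 2 and 63.0% (61.6 to 64.3) with Dox replicate 1, again the longer list. Over whole lists, 56.4% (55.7 to 57.2) of Dox replicate 2 peaks overlapped Dox replicate 1, against 1.55% after random shifts, and 19.6% of Dox replicate 1 peaks overlapped Dox replicate 2, against 0.55%. For PBS, 58.4% (57.5 to 59.3) of replicate 1 peaks overlapped replicate 2, against 0.7% after random shifts, and 28.4% of replicate 2 peaks overlapped replicate 1, against 0.36%. Of the PBS replicate 1 peaks, 67.9% overlapped the long list of Dox replicate 1. With the same number of top peaks from each list, 36.6% to 46.7% of peaks overlapped over all ordered pairs of libraries, within and between conditions. At that length Dox replicate 1 overlapped Dox replicate 2 by 39.7% and PBS replicate 2 by 41.6%, and PBS replicate 1 overlapped PBS replicate 2 by 42.5% and Dox replicate 1 by 46.7%.

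**Figure D1:**
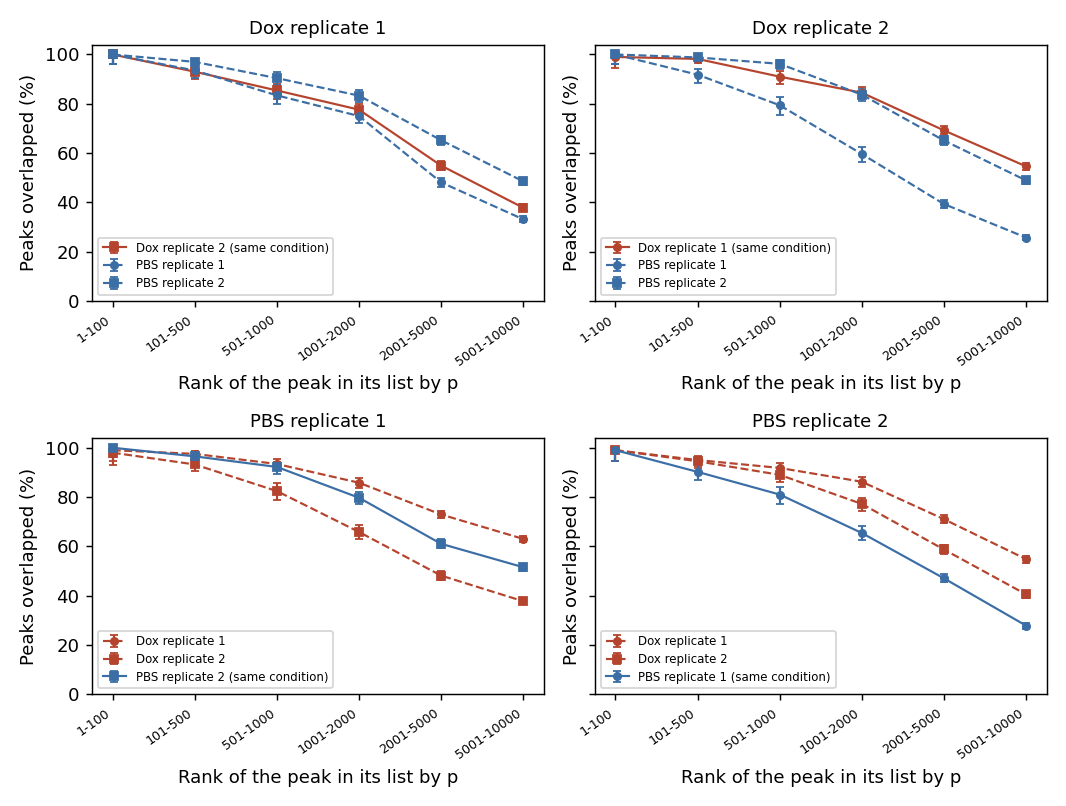
Share of the peaks of each library (vertical axis, per cent) that overlap a peak of each other library, by the rank of the peak by p in its own list (horizontal axis); points carry 95% Wilson intervals, red lines are Dox and blue lines PBS partners, and solid lines join libraries of the same condition. Nearly all of the first 100 peaks are found in the other libraries, and the overlap falls with rank; partner lists differ in length, from 11304 to 46658 peaks, and a longer list gives more overlap, so the heights of the lines do not compare conditions.

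The pairs of peaks matched between replicates gave 8784 Dox regions and 6244 PBS regions. Of the Dox regions, 3769 (42.9%) overlapped a PBS region, against 0.39% after random shifts, and of the PBS regions 3832 (61.4%) overlapped a Dox region, against 0.55% after random shifts. This left 5015 Dox-only and 2412 PBS-only regions. The leading Dox-only site, on chromosome X from 150712226 to 150712624, had an enrichment of 9.7-fold and 6.2-fold in the Dox libraries, and also held a peak of 5.9-fold in PBS replicate 2. Next came chromosome 11 from 117689869 to 117690249, with 5.8-fold and 6.3-fold enrichment in the Dox libraries, and chromosome 19 from 49464718 to 49466029, with 6.0-fold and 5.9-fold; each also held a peak in PBS replicate 2. Among the 10 leading Dox-only sites, 9 had a peak in 1 PBS library and 1 had none, the site on chromosome 4 from 190861745 to 190862045. In all 9 it was PBS replicate 2 that held the peak, and PBS replicate 1, the shortest list, that did not. On chromosome 2 from 242823265 to 242823919 that peak was 10.7-fold, with 7.6-fold and 4.9-fold in the Dox libraries. Since these sets leave out matched pairs of the other condition, a peak in both of its libraries was nearly excluded by definition. The leading PBS-only sites lay on chromosome 21 from 9825936 to 9826306, with 6.3-fold and 5.1-fold enrichment in the PBS libraries and 6.6-fold in Dox replicate 1, and on chromosome 1 from 144491007 to 144491605, with 5.2-fold and 4.6-fold in the PBS libraries. The site on chromosome 1 was the 1 of 10 leading PBS-only sites with no peak in either Dox library.

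Most Dox-only and PBS-only regions held a peak in at least 1 library of the other condition. Of the Dox-only regions 3029 (60.4%) overlapped a peak in a PBS library, and of the PBS-only regions 1819 (75.4%) overlapped a peak in a Dox library. At an IDR of at most 0.05 there were 2416 Dox and 937 PBS regions, of which 2278 (94.3%) and 874 (93.3%) overlapped a peak in a library of the other condition, against 1.36% and 2.57% after random shifts. By stricter measures fewer were shared: 71.2% of these Dox and 75.1% of these PBS regions overlapped a matched pair of the other condition at any IDR, and 22.2% and 57.7% overlapped one that also had an IDR of at most 0.05. The excess of Dox-only over PBS-only regions, 2603 with all pairs, depended on the libraries. Without PBS replicate 1 it became -13514 and without PBS replicate 2 it became -2042, since the remaining list then stood for the condition. Without Dox replicate 1 the excess was 10032 and without Dox replicate 2 it was 40078. No test across libraries applies to these sets, which are 1 per condition.

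The number of p53 peaks differed between Dox and PBS in opposite directions in the replicate numbers, and the difference of the means was smaller than the spread between the Dox replicates. The mean was 31650 ± 21225 peaks for Dox and 17141 ± 8255 for PBS (SD, n = 2 each; two-sided exact permutation p = 0.667, smallest possible p 0.33). Within replicate number 1, from passage 3, Dox had 35354 more peaks than PBS, a ratio of 4.13. Within replicate number 2, from passage 5, the difference was -6336 peaks, a ratio of 0.72. Peaks with q of at most 0.05 numbered 1703 and 806 for Dox and 289 and 1342 for PBS, with differences of 1414 within number 1 and -536 within number 2. Without Dox replicate 1 the difference of the means was -499 peaks.

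**Figure D2:**
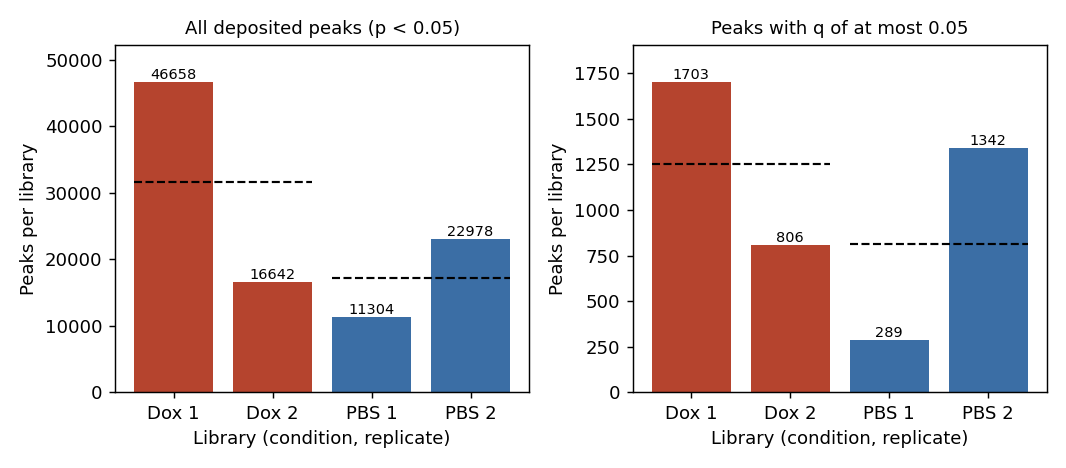
Peaks per library (vertical axis, number of peaks) for the 2 Dox libraries (red) and the 2 PBS libraries (blue), for all peaks on the left and for peaks with q of at most 0.05 on the right; dashed lines are the means of each condition. Dox replicate 1 has the longest list with 46658 peaks, and PBS replicate 2 with 22978 peaks lies above Dox replicate 2 with 16642.

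The 4 lists merged into 63890 sites, of which 3840 (6.0%) were found in all 4 libraries and 30961 (48.5%) in Dox replicate 1 alone. Sites in both Dox libraries and in neither PBS library numbered 1986, and sites in both PBS libraries and in neither Dox library 593, together 2579. The split by replicate number gave 3000 such sites, 1464 for number 1 and 1536 for number 2. The crossed split gave 3401. With the same number of top peaks from each list, 791 sites were exclusive to the Dox pair and 792 to the PBS pair, together 1583, against 2235 for the split by replicate number and 1285 for the crossed split. In neither case did the split by treatment give the most sites, and 3 splits allow no p under 0.05. At −log10 q minimums of 2 and 3, tried after the data were seen, the treatment split exceeded the split by number by 2 sites. The crossed split was the largest there, with 140 and 106 sites against 74 and 51 by treatment.

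**Figure D3:**
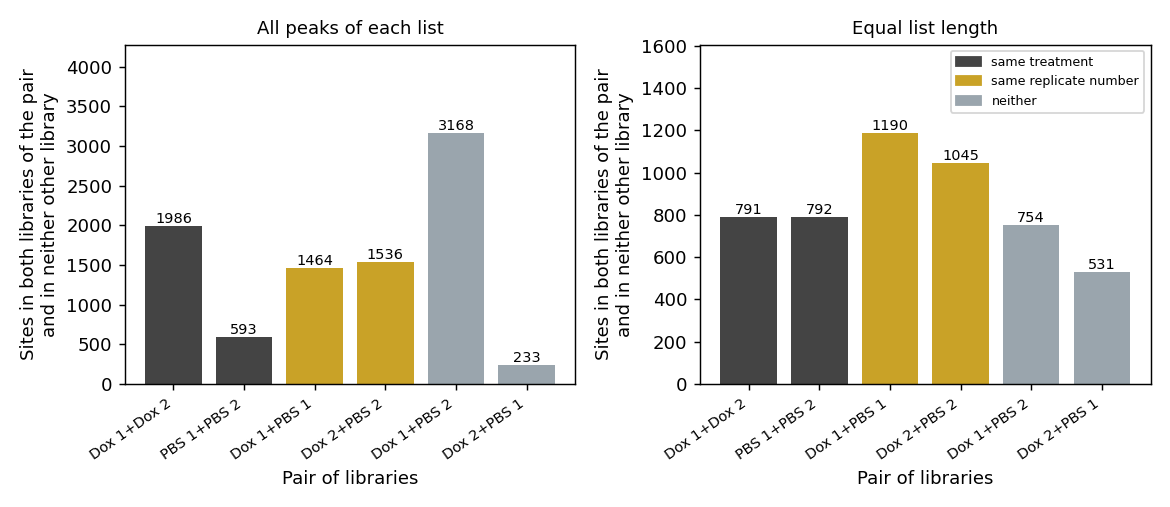
Number of sites found in both libraries of a pair and in neither other library (vertical axis) for each of the 6 pairs of libraries (horizontal axis), with all peaks on the left and with the same number of top peaks from each list on the right. At equal list length the Dox pair has 791 and the PBS pair 792 such sites, below the 1190 and 1045 of the pairs that share a replicate number.

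Sites with q of at most 0.05 in both libraries of a condition held a peak at any q in the other condition with few exceptions. Of 541 sites with q of at most 0.05 in both Dox libraries, 515 (95.2%) had a peak in both PBS libraries and 2 had a peak in neither. These were the site on chromosome 4 from 190861745 to 190862045, with 5.98-fold and 5.53-fold enrichment in Dox replicates 1 and 2, and a site on chromosome 5 from 1073478 to 1074285, with 4.98-fold and 5.23-fold. Of 256 sites with q of at most 0.05 in both PBS libraries, 249 (97.3%) had a peak in both Dox libraries, and 1 had a peak in neither, on chromosome 1 from 144491007 to 144491605. By the same count, 9 sites were exclusive to the libraries of replicate number 2, 2 to those of number 1, 5 to Dox replicate 1 with PBS replicate 2, and 0 to Dox replicate 2 with PBS replicate 1. The split by treatment thus gave fewer such sites than either other split. These counts are small, and absence was judged against lists of 11304 to 46658 peaks. The splits thus had unlike chances of such sites, and no conclusion was drawn from their order. The threshold was chosen after counts at several had been seen: at −log10 q minimums of 1, 2 and 3 the Dox pair had 3, 2 and 1 exclusive sites, the PBS pair 1, 1 and 0, and the libraries of number 2 had 12, 4 and 2. More sites differed when every library had to reach a −log10 q of 1.3. Then 206 sites were in all 4 libraries, 92 were exclusive to the Dox pair and 9 to the PBS pair. The split by treatment then gave 101 sites, the split by number 111 and the crossed split 241. The lists at q of at most 0.05 ran from 289 to 1703 peaks, so these counts do not compare conditions.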

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

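The tests of ChIP background height, of the direction within each replicate number and of the ratio of sites with 1 minimum height as a sign of more sites after doxorubicin were chosen after the result was seen, and the minimum height itself was added after the lists had been read. The difference in peak number between Dox and PBS had opposite signs in the replicate numbers: 35354 more peaks in Dox within number 1, from passage 3, and -6336 within number 2, from passage 5. Peaks with q of at most 0.05 showed the same opposition, with 1414 within number 1 and -536 within number 2. They are part of the same lists and are not separate support. PBS replicate 1, the shortest list, had the highest ChIP-to-control ratio, 5.37, and what this ratio did to its counts was not tested. With the common minimum height the differences were 18635 within number 1 and -7172 within number 2. Each difference rests on 1 library per condition, so the difference between the numbers was not tested.

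The list of Dox replicate 1 was 2.8 times as long as that of Dox replicate 2. With 1 minimum height over the estimated background for all lists the ratio was still 2.03. If the formulas assumed for fold and p hold, a lower height over that background was thus not the whole cause. The height a peak needs also depends on the caller's local background, which was not made equal. The p of 63.5% and 41.1% of peaks in Dox replicates 1 and 2 lay on the steps of the estimated background. Under the same formulas, a deeper ChIP library is argued against by a ratio of background heights of 0.99. The ratio was 1.04 after division by the shortest peak length as a stand-in for the read extension. More peaks after doxorubicin goes against the sign within number 2, -6336 peaks, but that value was seen before, rests on 1 library per condition and is smaller than the SD of 8255 between the PBS replicates, so it excludes nothing. An effect of doxorubicin, at passage 3 alone or at both passages, stays open, since passage, replicate number and single libraries cannot be separated.

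Libraries of the same replicate number shared more exclusive sites than libraries of the same treatment. The crossed pairs, which share neither, had more still with all peaks, 3401 against 3000 for the split by number. The same held at a −log10 q of at least 5, with 46 against 27. At equal list length the crossed pairs had fewer, 1285 against 2235. Different lowest heights were tested as a cause of the excess of the split by number over the split by treatment. With 1 minimum height and equal list lengths the excess was 653 sites, against 123.0 for 2 Poisson standard errors, which treat sites as independent. Equal length cut the longer lists again by p, so lowest heights were not held equal there and are not excluded by that test. With 1 minimum height alone, on lists of unequal length, 2831 sites were exclusive to a number and 2160 to a treatment. The excess depended on the threshold, however, since at −log10 q minimums of 2 and 3 the treatment split was larger by 2 sites. The libraries of a number share their passage, and may also share handling on the same occasion. The correlation over sites of the replicate differences in Dox with those in PBS was 0.074 at equal list length, between the bounds of 0 and 0.1 set beforehand. Other equal lengths, tried along the way, gave 0.067 (top 5000 peaks) to 0.108 (top 500), the latter above the bound. At −log10 q minimums of 1 to 3 it was 0.28 to 0.327, on lists of unequal length. Something shared by a replicate number and chance sharing cannot be told apart with 1 library per condition and number.

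At an IDR of at most 0.05 the Dox pairs outnumbered the PBS pairs by 2.58 times, with 2416 against 937. The ratio of sites in both Dox to sites in both PBS libraries, another quantity, moved from 1.4 to 1.29 with 1 minimum height; since it lay under the bound of 1.5 from the start, that test decides nothing, and the high lowest peak of PBS replicate 1 and more binding sites after doxorubicin cannot be told apart. A test of the latter written before its result was seen, at 1 minimum height and equal list length, gave 0.99, under the bound of 1.2 that counted against it. That test was set aside after its value was seen and replaced by the one without the length limit, because lists of equal length cap the number of sites each condition can show. It speaks against more sites in both Dox libraries among equally long lists, and says nothing of the IDR pairs or of sites beyond that length.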

How the results depend on the processing

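The common minimum height, the IDR limit of 0.05, the ranking by p, the lists of 500 to 5000 peaks and the −log10 q minimums of 1 to 3 were chosen after the data were seen. Unless a construction is named, the cause of a change was not tested. Depth is not given, so a site without a peak was not called at that library's threshold, which does not show that p53 was absent.

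The mean peak number stayed higher in Dox at a −log10 q of at least 5 (73 peaks), with the common height (5731.5) and with the replicate block (14509, exact sign-flip p = 1.0, smallest possible p 0.5). Leaving out 1 library at a time gave -499 to 29517, with the negative value without Dox replicate 1. Over sites, the replicate 1 minus 2 differences of Dox and PBS correlated by 0.213 with all peaks and 0.074 at equal list length. The value with all peaks comes from lists of unequal length and is no measure of sharing by replicate number. With all peaks, fewer sites were exclusive to a replicate number (3000) than to a crossed pair (3401). With the block by replicate number, number 1 alone gave 38563 sites in Dox and not PBS and 3371 in PBS and not Dox, and number 2 alone gave 7473 and 13623, since 1 library then stood for each condition.

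Replicate overlap fell to 31.2% for Dox and 35.7% for PBS with 50% reciprocal overlap and rose to 81.8% and 92.4% at a −log10 q of at least 5; with the common height PBS gave 57.1%. Dox-only, PBS-only and shared regions numbered 836, 111 and 346 at an IDR of at most 0.01 (excess 725), and 1879, 396 and 537 at 0.05 (excess 1483). Regions with no peak in either library of the other condition numbered 1986 and 593 (excess 1393). At equal length there were 2967 Dox-only regions (excess 76, which equal totals hold near 0 by construction), and with midpoints within 100 bp 4130 PBS-only and 2114 shared regions. Leaving out 1 library at a time gave 2495 to 41132 Dox-only, 1054 to 16009 PBS-only and 4315 to 6289 shared regions, and an excess of -13514 to 40078, negative without PBS replicate 1 or PBS replicate 2 (-2042).

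Sites exclusive to the Dox pair numbered 791 at equal list length, 781 with the common height as well, and 16 at a −log10 q of at least 5, where the PBS pair had 4, the split by number 27 and the crossed split 46. The crossed split had 1285 at equal length and 1288 with the common height as well. The treatment split was smaller than the split by number under all list lengths, heights, merging rules and thresholds tried but −log10 q minimums of 2 and 3, where the difference reversed to 2 sites each. Ranked by p, 5 of the 10 leading PBS-only sites, 8 of the Dox-only and 8 of the shared sites were kept. Gene lists, motif and location were not run, with their alternatives, since no hg19 sequence or annotation was used here.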

Other observations

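All analyses of this part were chosen after the data were seen. Over the span from the first to the last peak of a chromosome, which still counts gaps in between, the mean number of peaks per Mb at equal list length was 14.93 on chromosome 19, 14.27 on chromosome 22 and 9.07 on chromosome 17. It was 1.21 on chromosome 18 and 1.38 on chromosome 13. Counted from the chromosome start, chromosome 22 had 9.79 and chromosome 13 had 1.14, since their first peaks lay 16.1 and 19.6 Mb from the start. Chromosome 16 held 5.17% and 5.16% of the Dox peaks and 4.5% and 4.58% of the PBS peaks, and chromosome X 3.01% and 3.64% of the Dox peaks and 3.84% and 4.17% of the PBS peaks. Both Dox libraries lay above both PBS libraries on 6 of 23 chromosomes and below them on 5, and chance gives 7.7 separated chromosomes of 23; the exact permutation p of each was 0.33, the smallest possible with n = 2.

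Some 100 kb windows were crowded with peaks in all libraries at equal list length. On chromosome 1 from 228700001 to 228800000 there were 30 and 42 peaks in the Dox libraries and 37 and 38 in the PBS libraries. On chromosome X from 114900001 to 115000000 there were 35 and 35 in Dox and 31 and 29 in PBS. The 10 most crowded windows held 1.84% to 2.06% of each list. Sites within the first 20 kb of a chromosome were found in all 4 libraries on chromosome 1 (9928 to 10596), chromosome 5 (10256 to 11188 and 11423 to 11875) and chromosome 18 (9990 to 10347). The site on chromosome 1 had 7.14-fold and 5.95-fold enrichment in Dox and 12.7-fold and 8.05-fold in PBS.

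As a hypothesis, crowded windows may hold tandem copies at a fixed distance. The most frequent distance between summits in the Dox lists was tested for an excess in the PBS lists, against summits moved at random by up to 1500 bp. In 2 of the 10 windows it passed after Benjamini-Hochberg adjustment over the 10 windows. That is fewer than the 5 set for the hypothesis and more than the 0 set against it, and both bounds were chosen after the data were seen. On chromosome 1 from 228700001 to 228800000 the PBS lists had 31 summit pairs 4400 to 4500 bp apart, against 6.75 after random moves. The permutation p was 0.0001, the smallest that 10000 simulations can give, and the adjusted p was 0.001. This distance ranked 2 of 45 by frequency in the PBS lists, so it was not the most frequent there. On chromosome 1 from 161400001 to 161500000 there were 9 pairs 3800 to 3900 bp apart, against 3.04 (permutation p = 0.0034, adjusted p = 0.017). The Dox and PBS lists come from the same cell line, so a distance that recurs in both is not a separate test of copies in the genome, and the hypothesis stays open for all 10 windows.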
